A study of Mus musculus with 8 samples.

How the data were processed

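RNA sequencing measured gene expression in mouse CD8 T cells from the spleens of OT-I mice, whose T cells carry a transgenic receptor for an ovalbumin peptide. Per the series description, cells were kept with the peptide for 3 days, received a retroviral vector for TOXFL or TOXdeltaN at 24 h, and were sorted on day 5. Each vector also encoded GFP behind an internal ribosome entry site, so GFP marked the cells that carried it. GFP-negative cells and the brightest 20% of the GFP-positive cells of each kind of culture gave 4 groups of 2 libraries, 8 in all, grouped by the construct and GFP status in the labels. Per the labels' protocols, each library was made from 8 ng of total RNA with a SMART-Seq kit and Nextera tagmentation. This chemistry does not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. Cells carrying a vector with GFP alone were not analysed here.

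Per the submitters' processing notes, the authors used bcl2fastq 2.20, cutadapt with no version given, STAR 2.6.1 and RSEM 1.2.28 on the GRCm38 genome. The deposited values are RSEM estimated counts per gene, without normalisation, in whole numbers. The step that made them whole numbers and the annotation release are not stated. The table had 31907 rows, of which 92 were ERCC spike-in rows with 0 counts in every library, and the other 31815 were genes. Symbols and coordinates were taken from GENCODE M21 for the same build. Of the gene identifiers, 31173 matched that release with their version and 31748 without it, and coordinates are given only where the version matched. There were 39 symbols carried by more than 1 identifier.

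Total counts per library lay between 25059112 and 31240067. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by group, which left 13329, and libraries were scaled with TMM factors between 0.9894 and 1.0203. The main test was the edgeR quasi-likelihood F-test on a model of group means, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. All 4 groups shared 1 estimate of the spread because 2 libraries per group leave few degrees of freedom. The replicate spread was unequal (chi-square per degree of freedom from 11.6 to 40.2), so it can be too large or too small for a comparison. The numbers of genes called with each construct therefore do not measure which effect is larger. The biological coefficient of variation was 0.1321. A gene is described as called when its adjusted p lay under the threshold in the fit named. CPM values (counts scaled to 1e6 per library) use the TMM factors and are given as mean ± SD.

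The comparisons were GFP-positive against GFP-negative cells for each construct, the difference of those effects (TOXFL minus TOXdeltaN), the GFP-positive groups against each other, and the GFP-negative groups against each other. The average of the construct effects and the difference between replicate numbers were added after the data were seen. Genes called in both construct comparisons were set against the overlap of independent lists. The comparisons of the constructs use separate libraries, so no controls are shared between them. They do share the estimate of each gene's spread. A gene with a low estimate is called more readily in both, so the overlap of independent lists can be too low a reference. The correlation of the effects is across genes with a mean over 8 CPM, and genes are not independent replicates.

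Every group has a replicate 1 and a replicate 2. The labels do not say what the number marks. Whether the numbers pair the libraries was judged by correlating, across genes, the deviations of same-numbered libraries from their group means. This was done before the calls of any fit were compared. All 6 pairs of groups had positive correlations, from 0.168 to 0.241 over the tested genes and from 0.241 to 0.479 over the 9042 genes above 8 CPM. The third principal component, with 11% of the variance, separated the numbers. The pairing is therefore inferred from the data and not from the labels. On the first principal component replicate 2 lay above replicate 1 in every group. A single axis of variation, aligned with the numbers without any pairing, could give the same signs, so these values do not settle the pairing. The fit with the replicate number as a block, called the blocked fit, is given beside a result where it changed a call or moved a count by over 1.5 times. Its biological coefficient of variation was 0.0958.

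The 27 fixed gene lists covered inhibitory receptors, cytotoxic effector genes, effector cytokines and chemokines, naive and memory genes, terminal effector and NK-receptor genes, tissue residency genes, TCR-induced transcription factors, the TOX family, cytokine receptors, chemokine receptors and adhesion molecules, CD4 T helper genes, costimulatory receptors, DNA replication, mitosis, ribosome biogenesis, glycolysis, oxidative phosphorylation, cholesterol synthesis, interferon-stimulated genes, apoptosis and p53 target genes, unfolded protein and amino acid stress genes, the HBO1 complex, mitochondrially encoded genes, and markers of B cells, of myeloid and dendritic cells, of CD4 T, NK and gamma-delta T cells, and of erythroid cells. Lists with fewer than 3 tested members were not tested, which left 25. The test was camera from limma 3.58.1 with a preset correlation of 0.01 between genes and a prior count of 2, with Benjamini-Hochberg adjustment over the lists within a comparison. It was repeated with the correlation estimated for each list, and no list was called in that repeat in any comparison. Camera compares a list with the other genes.

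Named genes were chosen by a rule. For each construct comparison it took the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 10 CPM in the higher group and with both libraries of one group above both of the other. Tox itself, numbered gene models, pseudogenes and receptor segments were left out of the ranking. The rule added up to 4 called members of each list, or the members with the highest CPM where none was called, and always Tox, Tox2, Tox3, Tox4, Pdcd1, Tcf7, Gzmb and Ifng. The same rule was repeated on the blocked fit. The design, gene lists, naming rule and the settings in the first sentence of the next paragraph were fixed before the data were examined.

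The other settings tried were DESeq2 size factors or library size alone in place of TMM, no low-count filter, a filter at a mean of 5 CPM, DESeq2 1.42.0, limma-voom, the replicate block over all libraries or within each construct, a fit of only the groups compared, and the omission of each library in turn. Settings chosen after the data were seen were a correction for transcript length, in which a spline with 4 degrees of freedom of each library's deviation against transcript length was removed through offsets, the same correction in the blocked fit, and the earlier settings repeated on the blocked fit.

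The steps were tested on simulated data. Counts were drawn around the means of the replicate numbers with the spreads of the blocked fit, so the block was correct by construction. The better recovery of the blocked fit therefore does not show that the block holds for the real libraries. Of the 13329 genes drawn, the same filter kept 13071 for testing. The changed genes were picked only from those above a minimum mean count. For TOXFL-positive against TOXFL-negative cells, the fit without a block recovered 13.4%, 71.6% and 93.9% of genes changed by a log2 of 0.5, 1 and 2, with 0 calls among unchanged genes. The blocked fit recovered 46.3%, 88.1% and 98.5%, with 13 calls among unchanged genes. For the difference of the effects, also over 13071 genes, the fit without a block recovered 4.5%, 38.8% and 89.4% with 0 false calls, and the blocked fit 22.4%, 74.6% and 93.9% with 7. For TOXFL in the blocked fit, a simulated list of 20 genes raised by 0.5 had an adjusted p of 2.93e-44 with the preset and 0.0122 with the estimated correlation, and 0 of 20 random lists were called. The simulated genes varied independently of each other. These values therefore do not show that the preset correlation holds for real lists, whose genes can vary together. For TOXdeltaN, a simulated length trend in both positive libraries, with no gene changed among 13329, gave 639 calls without the length correction and 1 with it. The simulated log2 slope per doubling of length was −0.2 in both, while the real replicates 1 and 2 had −0.0125 and −0.1794. The trend was built on the same lengths that the correction uses, so its removal followed from the design. It does not show that the correction suits the real libraries.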

Results

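The libraries came from OT-I CD8 T cells that carried a retroviral vector for a TOX protein or did not. TOX is a nuclear protein with an HMG-box DNA-binding domain, and its gene gives rise to 2 proteins, represented here by the full-length form (TOXFL) and by TOXdeltaN. The 4 groups were TOXFL-negative, TOXFL-positive, TOXdeltaN-negative and TOXdeltaN-positive cells, where positive cells had the marker GFP of the vector, with 2 libraries each. Total counts were 26748159 and 28509777 in the TOXFL-negative libraries, 29521936 and 31240067 in the TOXFL-positive, 29547661 and 29883258 in the TOXdeltaN-negative, and 29456835 and 25059112 in the TOXdeltaN-positive libraries. Between 16577 and 16943 genes had a count in a library, and the 10 most abundant genes took 3.99% to 4.96% of the counts. The labels do not state whether the 2 libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical. Replicates differed by more than counting error in every group, with a chi-square per degree of freedom from 11.6 in the TOXFL-negative to 40.2 in the TOXdeltaN-positive libraries.

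Tox was measured first because it checks the labels. Tox (ENSMUSG00000041272.11, GRCm38 chromosome 4, 6686353 to 6991557) stood at 25.05 and 34.37 CPM in the TOXFL-negative libraries and at 104.8 and 126.3 CPM in the TOXFL-positive libraries. It stood at 21.8 and 32.16 CPM in the TOXdeltaN-negative and at 107.2 and 82.9 CPM in the TOXdeltaN-positive libraries. These counts hold reads of the endogenous gene and of the vector together. Tox rose by a log2 of 1.96 with TOXFL (SE 0.219, adjusted p = 0.0297, n = 2 per group) and by 1.82 with TOXdeltaN (SE 0.219, adjusted p = 0.0419). The TOXFL call held in 5 of the 8 omissions of a library and the TOXdeltaN call in 1 of 8, without TOXdeltaN-positive replicate 1, with adjusted p up to 0.533 and 0.311. A fit of the TOXdeltaN groups alone gave an adjusted p of 0.259. Among its relatives, Tox4 did not change (log2 −0.04, adjusted p = 0.911 with TOXFL, and −0.15, adjusted p = 0.565 with TOXdeltaN). Tox2 had 2 to 12 counts and Tox3 0 to 5 counts per library, too few to test, so only 2 members of the TOX family list were tested.

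**Figure D1:**
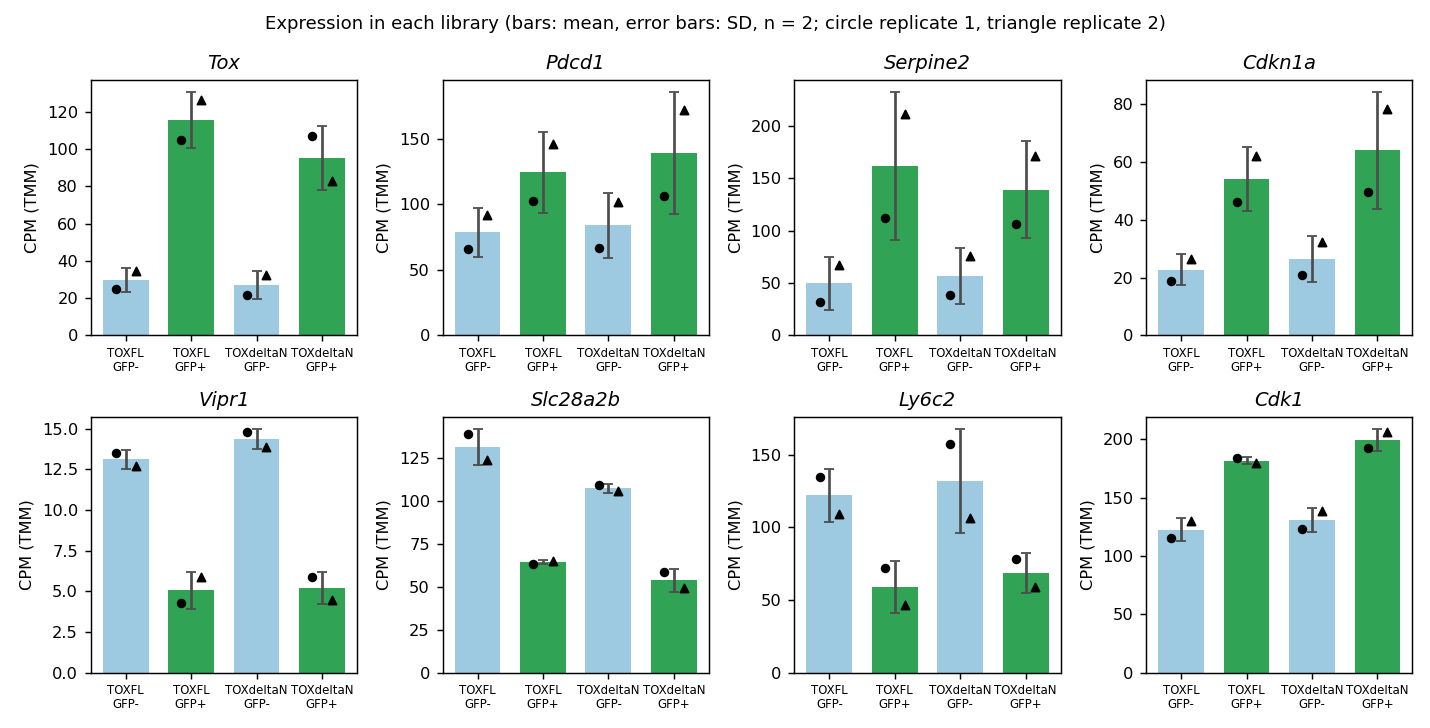
CPM after TMM scaling of 8 genes in every library, with bars for the mean of each group, error bars for the SD (n = 2), circles for replicate 1 and triangles for replicate 2. Tox, Pdcd1, Serpine2, Cdkn1a and Cdk1 were higher, and Vipr1, Slc28a2b and Ly6c2 lower, in both GFP-positive libraries than in both GFP-negative libraries of each construct.

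TOXFL-positive cells were compared with TOXFL-negative cells, a comparison that holds TOXFL, the vector and the sort on GFP together. Besides Tox, the cell-surface tetraspanin Cd81 (ENSMUSG00000037706.17, chromosome 7, 143052739 to 143067934) rose from 6.43 ± 0.023 to 15.96 ± 0.873 CPM (log2 1.31, SE 0.137, adjusted p = 0.0297). The nucleoside transporter gene Slc28a2b (ENSMUSG00000079071.2, chromosome 2, 122484941 to 122528040) fell from 131 ± 10.3 to 64.3 ± 1.18 CPM (log2 −1.03, SE 0.11, adjusted p = 0.0297). The RNA-binding protein gene Taf15 (ENSMUSG00000020680.15, chromosome 11, 83473086 to 83506743) fell from 11.98 ± 1.56 to 2.81 ± 1.0 CPM (log2 −2.09, SE 0.261, adjusted p = 0.0399). The histone methyltransferase gene Kmt2a fell by a log2 of 0.77 (SE 0.0975) and the interferon-inducible GTPase gene Gbp10 by 0.75 (SE 0.0939), both with an adjusted p of 0.0399. Slc28a2b has a near-identical neighbour in Slc28a2 and Gbp10 in other Gbp genes, so the split of reads between copies is uncertain. These 6 genes, 2 higher and 4 lower, were all that edgeR called among 13329, while 1790 had an unadjusted p under 0.05 and DESeq2 called 318. Kmt2a was no longer called after the length correction (adjusted p = 0.0981), Taf15 not by limma-voom (adjusted p = 0.057), and Cd81, Taf15, Kmt2a and Gbp10 not in a fit of these groups alone (adjusted p = 0.0867). Each call ended in some omission of a library, with adjusted p up to 0.533. The count was 0 without TOXFL-negative replicate 1 or 2 or TOXFL-positive replicate 2, 1 without TOXdeltaN-negative replicate 1 or 2, 38 without TOXFL-positive replicate 1, and 122 and 120 without TOXdeltaN-positive replicates 1 and 2.

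In the blocked fit 464 genes were called with TOXFL, 201 higher and 263 lower, and with the length correction 321 higher and 286 lower. Among the genes ranked by the naming rule, which leaves out Tox, the opioid peptide gene Penk rose the most (log2 2.24, SE 0.193, adjusted p = 0.0011). It was followed by the protease inhibitor gene Serpine2 (ENSMUSG00000026249.10, chromosome 1, 79794197 to 79861180), which went from 49.5 ± 25 to 162 ± 70.8 CPM (log2 1.73, SE 0.104, adjusted p = 0.00017). Ier5l, Asb2, Tnfsf4, Cdkn1a, Car2, Tg and Tubb6 rose by 1.48, 1.45, 1.27, 1.26, 1.21, 1.197 and 1.10. Among surface and signalling genes of T cells, the inhibitory receptor genes Pdcd1 (log2 0.66, adjusted p = 0.00725) and Cd160 (log2 0.65, adjusted p = 0.00534) rose, as did the chemokine genes Xcl1 (log2 0.64, adjusted p = 0.0289) and Ccl3 (log2 0.68, adjusted p = 0.0343). S1pr1, which encodes a receptor for lymphocyte egress, the transcription factor gene Klf2 and the cytokine receptor gene Il18r1 fell (log2 −0.64, −0.44 and −0.66). The strongest falls besides Taf15 were Tatdn2 (log2 −1.87), Sun2 (−1.75), Stk11 (−1.49), Npm3 (−1.42), Max (−1.41), Vipr1 (−1.37), Dhx9 (−1.29), Emd (−1.17) and Ddx17 (−1.15), and the nuclear receptor gene Nr4a3 also fell (log2 −1.14, adjusted p = 0.0119). Of the 23 tested TCR-induced transcription factors, Nr4a3 alone was called lower in this fit, and 2 were called higher. Npm3 stood at 17.7 and 6.68 CPM in TOXFL-positive replicates 1 and 2, Max at 56.5 and 27.5, and Stk11 at 28.2 and 15.3. Emd stood at 36.1 and 19.1 CPM and Ddx17 at 42.5 and 23.3 in these libraries. Both lay below both TOXFL-negative libraries for these genes, but the sizes of the falls leaned on replicate 2. The libraries were closer for Tatdn2 (4.7 and 2.89) and Dhx9 (64.8 and 43.2). Apart from Taf15, none of the genes in this paragraph was called in the fit without the block. Tcf7 (log2 −0.20, adjusted p = 0.452), Gzmb (log2 0.22, adjusted p = 0.336) and Ifng (log2 0.21, adjusted p = 0.828) were not called in either fit. The blocked count was 36 and 30 without TOXFL-negative replicates 1 and 2, 150 and 35 without TOXFL-positive replicates 1 and 2, 155 and 137 without TOXdeltaN-negative replicates 1 and 2, and 1772 and 1749 without TOXdeltaN-positive replicates 1 and 2.

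Cell-division genes gave the strongest list result with TOXFL. The mitosis genes had a median log2 fold change of 0.49 (adjusted p = 2.46e-23, and adjusted p = 0.349 with an estimated correlation). Of its 24 members, 0 were called over all genes and 23 when adjusted over the list alone, and in the blocked fit 15 and 23, among them Cdk1 (log2 0.57), Bub1, Nek2 and Birc5. The DNA replication genes had a median of 0.30 (adjusted p = 5.42e-13, and adjusted p = 0.349 with an estimated correlation), with 13 of 24 called when adjusted over the list alone and, in the blocked fit, 5 over all genes, including Rrm2 and Tyms. Cholesterol synthesis genes (median 0.24, adjusted p = 1.38e-05), unfolded protein and amino acid stress genes (0.15, adjusted p = 0.000167), oxidative phosphorylation genes (0.0927, adjusted p = 0.00224), effector cytokines and chemokines (0.29, adjusted p = 0.00394) and apoptosis and p53 target genes (0.20, adjusted p = 0.0402) were also called higher. None of these was called with an estimated correlation (adjusted p = 0.373, 0.517, 0.675, 0.373 and 0.349). Lower were the mitochondrially encoded genes (median −0.58, adjusted p = 6.47e-09), the naive and memory genes (−0.24, adjusted p = 1.14e-05) and the interferon-stimulated genes (−0.30, adjusted p = 0.000916). They had adjusted p = 0.442, 0.167 and 0.517 with an estimated correlation. When adjusted over the list alone, 8 of 13 mitochondrially encoded genes and 2 of 18 naive and memory genes were called lower.

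Several TOXFL list results rested on 1 library. Without TOXFL-negative replicate 1 the oxidative phosphorylation genes (adjusted p = 0.144), the unfolded protein and amino acid stress genes (adjusted p = 0.0661) and the apoptosis and p53 target genes (adjusted p = 0.0911) were not called. Without TOXFL-positive replicate 1 the effector cytokines and chemokines were not called (adjusted p = 0.0575). Without TOXFL-positive replicate 2 the interferon-stimulated genes (adjusted p = 0.0642) and the apoptosis and p53 target genes (adjusted p = 0.191) were not called. The inhibitory receptors had a median of 0.28 and were called in the blocked fit (adjusted p = 0.0775 without and 0.0103 with the block), and without TOXFL-negative replicate 2 (adjusted p = 0.0114) or TOXFL-positive replicate 1 (0.0243). Glycolysis genes (median 0.10) followed the same course, with adjusted p = 0.122 and 0.011, and 0.00839 and 0.0173 without those libraries. The cytokine receptors (median −0.11) had adjusted p = 0.0892 without and 0.0307 with the block, and 0.0431 and 0.0443 without TOXdeltaN-positive replicates 1 and 2. The chemokine receptors and adhesion molecules (median −0.076) had adjusted p = 0.233 and, with the block, 0.0337. With an estimated correlation in the blocked fit, these 4 lists had adjusted p = 0.194, 0.383, 0.521 and 0.383.

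The other lists were not called with TOXFL in either fit. Cytotoxic effector genes had a median of 0.16 and an adjusted p of 0.0775, or 0.0183 without TOXFL-positive replicate 2. Tissue residency genes and TCR-induced transcription factors both had a median of 0.0314 and an adjusted p of 0.593. Costimulatory receptors stood at 0.0892 (adjusted p = 0.954) and the HBO1 complex, an acetyltransferase, at −0.0616 (adjusted p = 0.276). For the terminal effector and NK-receptor genes the median was 0.12 and the mean −0.00525, and the test pointed up (adjusted p = 0.593). The CD4 T helper genes (adjusted p = 0.722) and the ribosome biogenesis genes (adjusted p = 0.954) had medians whose sign changed with the scaling. Among markers of other cells, those of myeloid and dendritic cells (median 0.23, adjusted p = 0.413), of CD4 T, NK and gamma-delta T cells (−0.54, adjusted p = 0.593) and of erythroid cells (−0.0451, adjusted p = 0.66) were not called. Of the B cell markers only Cd22 and Cd79b could be tested, and neither was called.

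TOXdeltaN-positive cells were compared with TOXdeltaN-negative cells in the same way. Slc28a2b fell from 107 ± 2.55 to 53.8 ± 6.64 CPM (log2 −0.99, SE 0.11, adjusted p = 0.0419). Gbp10 fell from 58.8 ± 0.0264 to 33.4 ± 2.17 CPM (log2 −0.82, SE 0.0951, adjusted p = 0.0419). With Tox, these were among the 4 genes that edgeR called, 1 higher and 3 lower, while 1632 had an unadjusted p under 0.05 and DESeq2 called 120. None of the 4 was called in a fit of these groups alone (adjusted p = 0.259). The calls of Slc28a2b and Gbp10 held without TOXdeltaN-positive replicate 1, when 1571 genes were called, and were lost with each of the other 7 omissions, when 0 genes were called, with adjusted p up to 0.311 and 0.374.

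In the blocked fit 220 genes were called with TOXdeltaN, 103 higher and 117 lower, and with the length correction 164 higher and 149 lower. Serpine2 rose from 56.7 ± 26.4 to 139 ± 46.3 CPM (log2 1.34, SE 0.103, adjusted p = 0.000772). The cell-cycle inhibitor gene Cdkn1a (ENSMUSG00000023067.14, chromosome 17, 29090976 to 29100727) rose from 26.5 ± 7.98 to 64.1 ± 20.3 CPM (log2 1.27, SE 0.0995, adjusted p = 0.000772). Asb2, Tubb6, Gzmc, Cd81, Ier5l, Tnfsf4, Mt1 and Phlda3 rose by 1.27, 1.15, 1.06, 1.03, 1.00, 0.98, 0.91 and 0.85. Pdcd1 (log2 0.72, adjusted p = 0.00655) and Cd160 (log2 0.57, adjusted p = 0.0126) rose here too. The largest falls were those of the neuropeptide receptor gene Vipr1 (log2 −1.47, adjusted p = 0.0104), Igfbp4 (log2 −1.11, adjusted p = 0.0012), Syt6 (−1.11), the interleukin-6 receptor gene Il6ra (−1.10), Ifi206 (−0.97), Cnr2 (−0.97), Ly6c2 (−0.93), St6gal1 (−0.93) and Art2b (−0.91), and S1pr1 and Klf2 fell by 0.71 and 0.38 on the log2 scale. Counts of Gzmc, Ifi206 and Ly6c2 are uncertain because each belongs to a family of close copies. Tcf7 (log2 −0.29, adjusted p = 0.357), Gzmb (log2 0.30, adjusted p = 0.324) and Ifng (log2 0.23, adjusted p = 0.788) were not called in either fit. The blocked count was 0 and 8 without TOXdeltaN-negative replicates 1 and 2, 49 and 47 without TOXFL-negative replicates 1 and 2, 114 without either TOXFL-positive library, and 2650 without TOXdeltaN-positive replicate 1.

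With TOXdeltaN the mitosis genes had a median of 0.36 (adjusted p = 5.6e-16, and adjusted p = 0.467 with an estimated correlation). Of 24 members, 15 were called when adjusted over the list alone and 0 over all genes, and the blocked fit called 6 over all genes, including Cdk1 (log2 0.61), Birc5, Ube2c and Cdc20. The DNA replication genes had a median of 0.26 (adjusted p = 2.46e-10, and adjusted p = 0.467 with an estimated correlation), with 10 of 24 called when adjusted over the list alone. Oxidative phosphorylation genes (0.19, adjusted p = 4.82e-06), cholesterol synthesis genes (0.16, adjusted p = 0.000907), unfolded protein and amino acid stress genes (0.11, adjusted p = 0.0131), effector cytokines and chemokines (0.20, adjusted p = 0.0131) and cytotoxic effector genes (0.0981, adjusted p = 0.0182) were called higher. With an estimated correlation these had adjusted p = 0.504, 0.504, 0.616, 0.467 and 0.467. In the blocked fit with the length correction, the oxidative phosphorylation genes had a median of 0.0652 and a mean of −0.00817 (adjusted p = 0.041), and the effector cytokines and chemokines (0.135, adjusted p = 0.288) and cytotoxic effector genes (0.0559, adjusted p = 0.278) were not called. Cytokine receptors (−0.28, adjusted p = 1.59e-06), naive and memory genes (−0.26, adjusted p = 1.4e-05) and interferon-stimulated genes (−0.31, adjusted p = 0.000358) were called lower. With an estimated correlation these had adjusted p = 0.467, 0.178 and 0.504. When adjusted over the list alone, 8 of 18 naive and memory genes and 4 of 23 cytokine receptors were called lower, against 1 and 0 over all genes. Without TOXdeltaN-positive replicate 2 the cytotoxic effector genes (adjusted p = 0.11), the effector cytokines and chemokines (adjusted p = 0.24) and the unfolded protein and amino acid stress genes (adjusted p = 0.132) were not called. Without TOXdeltaN-negative replicate 2 the first pair had adjusted p = 0.0611 and 0.0545, and without TOXdeltaN-negative replicate 1 the stress genes had adjusted p = 0.293.

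The blocked fit added 4 lists with TOXdeltaN: inhibitory receptors (median 0.105, adjusted p = 0.196 without and 0.0455 with the block), glycolysis genes (0.0966, adjusted p = 0.261 and 0.0279), chemokine receptors and adhesion molecules (−0.0984, adjusted p = 0.06 and 0.00845) and mitochondrially encoded genes (−0.195, adjusted p = 0.0544 and 0.0348). With an estimated correlation in that fit these had adjusted p = 0.305, 0.346, 0.305 and 0.677. Mitochondrially encoded genes were also called with library size alone (adjusted p = 0.0439) and without TOXFL-positive replicate 1 (0.000433), TOXFL-positive replicate 2 (0.00047) or TOXdeltaN-positive replicate 2 (0.0121). Without TOXdeltaN-positive replicate 1 the chemokine receptors and adhesion molecules (adjusted p = 0.0162), the glycolysis genes (0.0252) and the HBO1 complex (0.0263) were called, and without TOXdeltaN-negative replicate 2 the chemokine receptors and adhesion molecules (0.00832). With all libraries the HBO1 complex had a median of −0.16 (adjusted p = 0.229, and adjusted p = 0.648 with an estimated correlation). Apoptosis and p53 target genes (0.10, adjusted p = 0.261), terminal effector and NK-receptor genes (0.11, adjusted p = 0.229), CD4 T helper genes (0.0183, adjusted p = 0.546), TCR-induced transcription factors (0.00985, adjusted p = 0.861) and ribosome biogenesis genes (0.0364, adjusted p = 0.861) were not called in either fit. For the tissue residency genes the median was 0.0579 and the mean −0.017, with the test pointing up (adjusted p = 0.831), and for the costimulatory receptors the median was −0.0363 and the mean 0.108, with the test pointing down (adjusted p = 0.861). Markers of myeloid and dendritic cells (0.30, adjusted p = 0.177), of CD4 T, NK and gamma-delta T cells (−0.0975, adjusted p = 0.931) and of erythroid cells (0.20, adjusted p = 0.638) were not called.

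**Figure D2:**
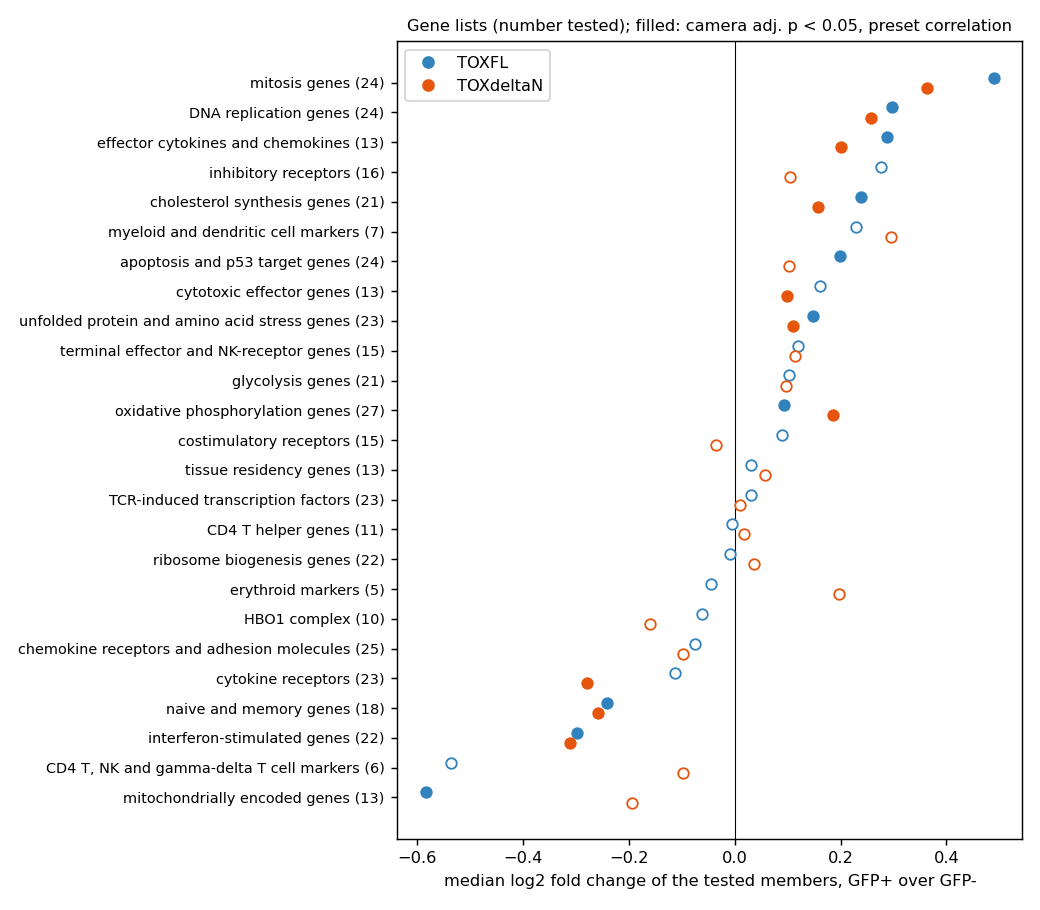
Median log2 fold change of GFP-positive over GFP-negative cells for the 25 tested lists, with the number of tested members in brackets, blue for TOXFL, orange for TOXdeltaN, and filled points for camera adjusted p under 0.05 with the preset correlation. Mitosis genes lay highest with both constructs (0.49 and 0.36), and no list was called with an estimated correlation.

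Genes called with both constructs are those that differed alike with GFP status, whether through TOX, the vector or the sort. In the fit without a block these were Tox, higher with both, and Slc28a2b and Gbp10, lower with both. In the blocked fit 148 genes were called in the same direction, of which 75 were higher against 1.55 for independent lists and 73 lower against 2.31, and 0 were called in opposite directions. The shared estimate of each gene's spread can raise this overlap. Shared calls were 0 and 7 without TOXdeltaN-negative replicates 1 and 2, 15 and 13 without TOXFL-negative replicates 1 and 2, 28 and 24 without TOXFL-positive replicates 1 and 2, and 860 and 265 without TOXdeltaN-positive replicates 1 and 2, with 22 opposite calls in the 860 case and 1 and 3 without TOXFL-positive replicate 1 and TOXdeltaN-positive replicate 2. The 148 genes included Serpine2, Cdkn1a, Cd81, Pdcd1, Cd160 and Cdk1 among the higher and Vipr1, Slc28a2b, S1pr1 and Klf2 among the lower genes. Of the 464 genes called with TOXFL in the blocked fit, 455 (98.1%) moved the same way with TOXdeltaN, with median sizes of 0.55 and 0.38 on the log2 scale. Of the 220 called with TOXdeltaN, 216 (98.2%) moved the same way with TOXFL, with median sizes of 0.55 and 0.49. Across the 9054 genes above 8 CPM the effects had a Pearson correlation of 0.687 and a Spearman correlation of 0.678. Averaged over both constructs, 179 genes were higher and 144 lower in GFP-positive cells without a block, and 805 and 892 in the blocked fit.

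**Figure D3:**
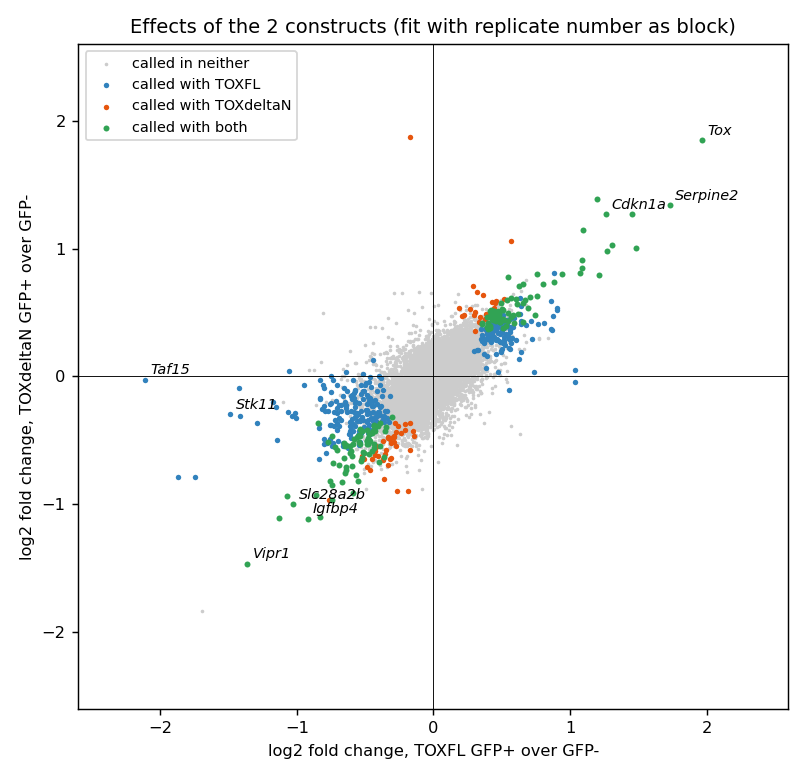
Log2 fold change of GFP-positive over GFP-negative cells with TOXFL (horizontal) and TOXdeltaN (vertical) in the blocked fit, 1 point per gene above 8 CPM, coloured by the comparison in which edgeR called it. Called genes lie mainly in the quadrants of equal sign, and Taf15 (log2 −2.11 with TOXFL and −0.02 with TOXdeltaN) lies near the horizontal axis.

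The difference of the effects asks for which genes the GFP-positive and GFP-negative cells differed more with one construct than with the other. Taf15 had the largest evidence, falling by 2.09 more on the log2 scale with TOXFL than with TOXdeltaN in the blocked fit (SE 0.247), but it was not called (adjusted p = 0.0989). Stk11 (log2 −1.19, SE 0.284) and Emd (log2 −0.98, SE 0.274), which fell with TOXFL in the blocked fit, each had an adjusted p of 0.989 for the difference. Tox, Pdcd1, Tcf7, Gzmb, Ifng and Tox4 differed by 0.14, −0.07, 0.09, −0.08, −0.02 and 0.11 with an adjusted p of 1 each. No gene was called by edgeR without a block (0, with 318 at an unadjusted p under 0.05) or with it (0, with 494), nor by limma-voom, and DESeq2 called 7 and, with the block, 6. Both unadjusted counts lay under a share of 0.05 of the 13329 tested genes, the share that would arise without any difference. Without the block 1 gene was called without TOXFL-positive replicate 1, and with the block 18 were called without TOXFL-positive replicate 1, 449 without TOXdeltaN-positive replicate 1 and 4 without TOXdeltaN-positive replicate 2. Lists called for the difference were the mitosis genes (median 0.11, adjusted p = 0.00655), whose median was 0.49 with TOXFL and 0.36 with TOXdeltaN, the cytokine receptors (0.13, adjusted p = 0.00224), with −0.11 and −0.28, and the mitochondrially encoded genes (−0.43, adjusted p = 2.23e-05), with −0.58 and −0.195, each with an adjusted p of 0.934 with an estimated correlation. Mitosis genes were also lower in TOXFL-negative than in TOXdeltaN-negative cells (median −0.0851), so part of their difference lay in the GFP-negative cells. Without TOXFL-positive replicate 2 the mitochondrially encoded genes (adjusted p = 0.851) and the mitosis genes (adjusted p = 0.0736) were not called. The mitosis genes were also not called without TOXFL-negative replicate 1 (adjusted p = 0.9), where their direction turned, TOXdeltaN-negative replicate 2 (0.227) or TOXdeltaN-positive replicate 2 (0.203), and the cytokine receptors not without TOXdeltaN-negative replicate 1 (0.0586) or TOXdeltaN-positive replicate 2 (0.254). With the block the mitosis genes were called without TOXFL-positive replicate 2 (0.00505) and not without TOXFL-negative replicate 1 (0.908), TOXFL-positive replicate 1 (0.248), TOXdeltaN-negative replicate 2 (0.0865) or TOXdeltaN-positive replicate 2 (0.924, where the median was −0.00889). There the cytokine receptors were called without TOXdeltaN-negative replicate 1 (0.00484) and not without TOXdeltaN-positive replicate 2 (0.0973), and the mitochondrially encoded genes not without TOXFL-positive replicate 2 (0.745) or TOXdeltaN-positive replicate 2 (0.051). Other lists were called only with a library left out: DNA replication genes (0.0381), cholesterol synthesis genes (0.0232) and stress genes (0.0232) without TOXFL-negative replicate 2, glycolysis and stress genes (0.0245 each) without TOXdeltaN-positive replicate 2, and oxidative phosphorylation genes without TOXFL-negative replicate 1 (0.0312) or TOXdeltaN-positive replicate 1 (0.000358).

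Setting the GFP-positive groups against each other compares the cells sorted for either vector directly. Taf15 stood at 2.81 ± 1.0 CPM in TOXFL-positive and 9.39 ± 1.36 CPM in TOXdeltaN-positive cells and was the only gene called in the blocked fit (log2 −1.76, SE 0.184, adjusted p = 0.0317), but limma-voom with the block called 0 genes (smallest adjusted p = 0.0953). It lies under the CPM minimum of the naming rule and was named after its values were seen. Without a block edgeR called 0 genes, with 768 at an unadjusted p under 0.05, limma-voom 0 and DESeq2 15. The count without a block was 704 without TOXdeltaN-positive replicate 1, 29 without TOXFL-positive replicate 1 and 1 without TOXdeltaN-negative replicate 1. With the block it was 1934 without TOXdeltaN-positive replicate 1, 76 without TOXFL-positive replicate 1, 2 without either TOXFL-negative library, and 0 without TOXFL-positive replicate 2 or TOXdeltaN-negative replicate 2.

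The GFP-negative groups were sorted without GFP signal, and their comparison gives the difference between the cultures in those cells. Oxidative phosphorylation genes (median −0.0848, adjusted p = 0.000661), mitosis genes (−0.0851, adjusted p = 0.013), effector cytokines and chemokines (−0.18, adjusted p = 0.0402) and unfolded protein and amino acid stress genes (−0.0487, adjusted p = 0.0402) were lower in TOXFL-negative than in TOXdeltaN-negative cells, with an adjusted p of 0.797 each with an estimated correlation. The blocked fit added glycolysis genes (adjusted p = 0.00839), TCR-induced transcription factors, DNA replication genes and mitochondrially encoded genes (adjusted p = 0.033 each), with adjusted p of 0.633 for the first 3 and 0.692 for the last with an estimated correlation. With the length correction in that fit the mitochondrially encoded genes (median −0.0527, adjusted p = 0.367) and the effector cytokines and chemokines (−0.127, adjusted p = 0.0773) were not called, while cholesterol synthesis genes (−0.0545, adjusted p = 0.0339) and, higher, interferon-stimulated genes (0.0399, adjusted p = 0.0358) were. Both of these lists had an adjusted p of 0.633 with an estimated correlation in the blocked fit without the length correction. No single gene was called by edgeR without a block (0, with 328 at an unadjusted p under 0.05) or with it (0, with 546), nor by limma-voom, while DESeq2 called 8 and, with the block, 6. These unadjusted counts too lay under a share of 0.05 of the 13329 tested genes. Without TOXdeltaN-negative replicate 1 edgeR called 1 gene in either fit, and with the block 8 and 7 without TOXdeltaN-positive replicates 1 and 2. Without TOXFL-negative replicate 1 the mitosis genes (adjusted p = 0.427) and the stress genes (0.886) turned upward, and the oxidative phosphorylation genes (0.427) and effector cytokines (0.135) were not called. Without TOXdeltaN-negative replicate 2 none of the 4 lists was called (adjusted p = 0.313, 0.515, 0.173 and 0.857 in the order above), and without TOXFL-negative replicate 2 the effector cytokines were not (0.0977). DNA replication genes were called lower without TOXFL-negative replicate 2 (0.000814), TOXdeltaN-negative replicate 1 (0.00498), TOXdeltaN-positive replicate 1 (0.0174) or TOXdeltaN-positive replicate 2 (0.0166). Without TOXFL-negative replicate 2 or TOXdeltaN-negative replicate 1, TCR-induced transcription factors (0.000872 and 0.000581), cholesterol synthesis genes (0.000358 and 0.0247) and glycolysis genes (0.000814 and 0.00498) were called lower and interferon-stimulated genes higher (0.0342 and 0.0115). Mitochondrially encoded genes were called lower without TOXFL-positive replicate 1 (0.000674) or 2 (0.000735).

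GFP-positive and GFP-negative libraries also differed in their trend with transcript length and in their share of mitochondrially encoded counts. The counts do not settle whether the length trend came from RNA quality, library preparation or the cells. The share holds largely the same reads as the mitochondrially encoded list and is no separate measure of it. The deviation of a gene from its mean over the libraries was correlated, across 9041 genes, with the length of its longest transcript. Spearman's rho was 0.43 and 0.415 in the TOXFL-negative and 0.268 and 0.145 in the TOXdeltaN-negative libraries, but −0.027 and −0.055 in the TOXFL-positive and −0.075 and −0.588 in the TOXdeltaN-positive libraries. Kmt2a, a gene with long transcripts, went from a log2 of −0.77 to −0.48 with TOXFL when length was corrected in the blocked fit, and Cdk1 from 0.57 to 0.61. Of the 464 genes called with TOXFL in the blocked fit, 376 (81.0%) were called in the same direction with the length correction, and of the 220 called with TOXdeltaN, 171 (77.7%). With that correction in the blocked fit, mitosis genes had medians of 0.48 with TOXFL and 0.34 with TOXdeltaN, and oxidative phosphorylation genes 0.0591 with TOXFL (adjusted p = 0.0621). The inhibitory receptors with TOXdeltaN (0.0966, adjusted p = 0.113) and the cytokine receptors with TOXFL (−0.0523, adjusted p = 0.0517) were then no longer called. Mitochondrially encoded genes then had a median of −0.627 with TOXFL and of −0.376 with TOXdeltaN (adjusted p = 1.6e-07), with 10 and 3 of 13 called lower over all genes. This list had, in the blocked fit without the length correction, adjusted p = 0.383 and 0.677 with an estimated correlation. Mitochondrially encoded genes took 0.83% of the counts in both TOXFL-negative libraries and 0.71% and 0.45% in the TOXFL-positive, and 0.91% and 0.89% in the TOXdeltaN-negative and 0.76% and 0.8% in the TOXdeltaN-positive libraries. TOXdeltaN-positive replicate 2 lay at the end of the first principal component (52.6% of the variance), at 23.9 against −16.7 to 9.85 in the other libraries.

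**Figure D4:**
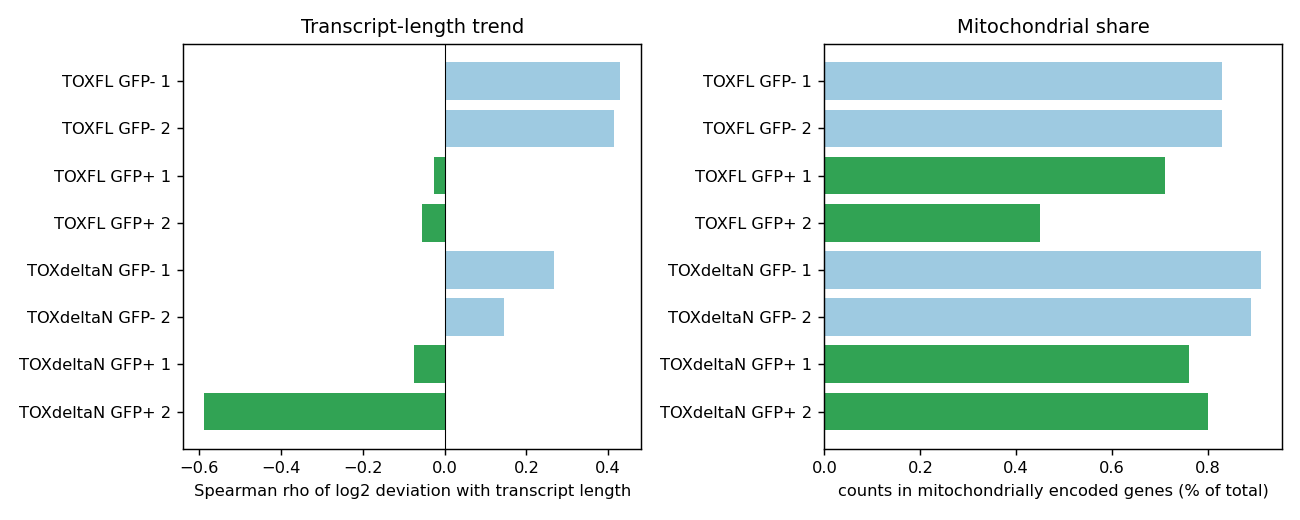
Spearman's rho of each gene's log2 deviation with transcript length (left) and the percent of counts in mitochondrially encoded genes (right), 1 bar per library, blue for GFP-negative and green for GFP-positive cells. All 4 GFP-negative libraries had a positive and all 4 GFP-positive libraries a negative rho, and TOXFL-positive replicate 2 had the lowest mitochondrial share, 0.45%.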

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

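All tests of explanations in this part were chosen after the results were seen. The gene lists whose response differed between the constructs were singled out because the list test called the difference of the effects. These were the cytokine receptors (median difference 0.129, adjusted p = 0.00224), the mitosis genes (0.111, adjusted p = 0.00655) and the mitochondrially encoded genes (−0.429, adjusted p = 2.23e-05). With an estimated correlation all 3 had an adjusted p of 0.934. The difference for the cytokine receptors was not called without TOXdeltaN-negative replicate 1 or TOXdeltaN-positive replicate 2 (adjusted p = 0.0586 and 0.254, while the blocked fit called it in the former case, with 0.00484, and not in the latter, with 0.0973), and that for the mitosis genes turned downward without TOXFL-negative replicate 1 (−0.0484, adjusted p = 0.9) and, in the blocked fit, also without TOXdeltaN-positive replicate 2 (−0.00889, adjusted p = 0.924). Between the GFP-negative groups the mitosis genes had a median of −0.0851 (adjusted p = 0.013, and adjusted p = 0.797 with an estimated correlation), a direction that turned without TOXFL-negative replicate 1 (0.427) and a call lost without TOXdeltaN-negative replicate 2 (0.515). The means of the mitosis list were 0.114 for the difference of the effects and −0.0673 between the GFP-negative groups. By these values more of the difference lay in the GFP-negative than in the GFP-positive cells. Both directions turned without TOXFL-negative replicate 1, and the cause was not tested. The cytokine receptors had a median of −0.113 with TOXFL and of −0.28 with TOXdeltaN, and the cause of that difference was not tested.

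For the mitochondrially encoded genes, a single library and the transcript-length trend were weighed. Without TOXFL-positive replicate 2, 3.85% of the median difference remained (−0.0165, adjusted p = 0.851), while without TOXFL-positive replicate 1 the median was −0.80 (adjusted p = 3.96e-24). Replicate 2 was chosen because it had the lowest mitochondrial share, so a smaller difference without it follows from that choice and shows no cause, only that the call rests on this library, and in the blocked fit it was also lost without TOXdeltaN-positive replicate 2 (adjusted p = 0.051). With the length correction 62.4% remained (−0.268, adjusted p = 0.00353), where a cause in the length trend was predicted to leave under 50%. An effect of TOXFL in a single culture was not tested and stays open.

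Of the genes called between GFP-positive and GFP-negative cells in the blocked fit, 81.0% with TOXFL and 77.7% with TOXdeltaN kept call and direction after the length correction, so the length trend alone did not account for most of them. Of the 35 ways to divide the 8 libraries evenly, 1, the real one, called as many genes (536), the highest other was the division by replicate number (84), and among the 18 that share the replicate numbers evenly the highest other called 1, though 18 are too few for a share under 0.05. Retroviral vectors enter dividing cells, and the mitosis genes were called higher as a list with both constructs, with 0.363 as the lower median, but not with an estimated correlation (adjusted p = 0.349 with TOXFL and 0.467 with TOXdeltaN). Effects of TOX and of vector entry on them cannot be told apart here, because that needs cells carrying a vector without TOX, which were not analysed here.

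The replicate numbers formed another pattern, because 403 genes differed between them in the blocked fit, a count that was 82 and 83 without TOXdeltaN-negative replicates 1 and 2, 145 and 144 without TOXFL-negative replicates 1 and 2, 146 and 153 without TOXFL-positive replicates 1 and 2, and 584 without either TOXdeltaN-positive library. Of the 35 divisions, 2 called at least as many genes as the replicate number (84 genes, itself included). The other was GFP status (536), which itself differs between the cells. No share under 0.05 could therefore be reached, and a random grouping was not excluded. The divisions that follow neither called at most 1 gene, but they left the GFP and replicate differences in their spread. After the length correction 93.5% of the 403 genes kept call and direction, where a cause in the length trend was predicted to leave under 50%. TCR-induced transcription factors were higher in replicate 2 (median 0.234, adjusted p = 1.37e-07, and adjusted p = 0.154 with an estimated correlation), though only 7 of 23 were called higher and 1, Jun, was called lower. A stronger T cell receptor signal in the replicate 2 libraries would raise this list, but the signal itself was not measured. Of 25 lists, 17 were called between the numbers, markers of other cell types among them, so other differences between the libraries stay open.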

How the results depend on the processing

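The length correction, the average effect and all settings repeated on the blocked fit were chosen after the data were seen. With TOXFL, 6 genes were called, and 464 with the replicate block, 607 with block and length correction, 519 with a block within construct, 318 with DESeq2, 678 without the low-count filter and 2 with only the groups compared. With TOXdeltaN, 4 genes became 220, 313, 285, 120, 516 and 0 in the same order. The average effect had 323 called genes, and 1697, 1593, 1801, 1064 and 1665 in the first 5 of these settings. Calls shared by both constructs went from 3 to 148, 216, 156, 63 and 233. For the difference of the effects, 0 became 7 with DESeq2 and 45 without the filter. Between the GFP-positive groups 0 became 1 with the block, 1 with block and length correction, 15 with DESeq2, 116 without the filter and 1 with only the groups compared, and between the GFP-negative groups 8 with DESeq2 and 37 without the filter. The cause was not tested.

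Settings repeated on the blocked fit moved its counts too. DESeq2, no filter and only the groups compared gave 749, 1048 and 1913 with TOXFL and 651, 947 and 657 with TOXdeltaN. DESeq2 and no filter gave 338 and 427 shared calls against 148, and 6 and 28 genes for the difference against 0. Between the GFP-positive groups the 1 call became 3, 199 and 78 with DESeq2, no filter and only the groups compared, and 0 with limma-voom. Between the GFP-negative groups the 0 calls became 6, 28 and 363. The 403 genes that differed between replicate numbers became 605 with DESeq2 and 910 with no filter. Among the 210 values of named genes the block added 97 calls and among 100 list results 12, all in the same direction, and with all libraries it changed no other call. Every group holds both replicate numbers, so the block leaves the estimated effects nearly unchanged and the equal direction is no separate support. Named genes were also chosen from the calls of the blocked fit, so their added calls follow in part from that choice.

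With 1 library left out, the remaining library of its group was assumed to vary like the other groups. The TOXFL count ran from 0 (without TOXFL-negative replicate 1) to 122 (without TOXdeltaN-positive replicate 1), the TOXdeltaN count from 0 to 1571, the difference from 0 to 1, the GFP-positive groups from 0 to 704, the GFP-negative groups from 0 to 1, the average from 5 to 2504 and the shared calls from 0 to 63. In the blocked fit they ran from 30 to 1772, 0 to 2650, 0 to 449, 0 to 1934, 0 to 8, 312 to 3681 and 0 to 860, and the genes differing between replicate numbers from 82 (without TOXdeltaN-negative replicate 1) to 584 (without either TOXdeltaN-positive library). Of the construct comparisons, all the highest counts above 100 came without TOXdeltaN-positive replicate 1. The correlation of the effects ran from 0.58 to 0.687, and in the blocked fit from 0.497 to 0.756. Without TOXFL-negative replicate 1 a direction turned for the mitosis genes, in the difference (adjusted p = 0.9) and between the GFP-negative groups (0.427), and for the unfolded protein and amino acid stress genes between the GFP-negative groups (0.886). In the blocked fit the mitosis difference also turned without TOXdeltaN-positive replicate 2 (0.924). The lowest adjusted p of these results came without TOXFL-negative replicate 2 (1.56e-08, 4.06e-09 and 0.000358), and without TOXdeltaN-negative replicate 2 the mitosis genes between the GFP-negative groups had 0.515.

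Scaling with DESeq2 size factors or library size, and a filter at 5 CPM, changed no call of a named gene. Of 100 list results, an estimated correlation removed all 27 calls, the length correction removed 9 and added 1 (the mitochondrially encoded genes with TOXdeltaN), and library size alone removed 1 and added 1. Depth was similar across libraries and limits chiefly genes of few counts, such as Tox2 and Tox3.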

Other observations

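The comparison of replicate numbers was chosen after the data were seen. Of the 23 TCR-induced transcription factors, 7 were called higher and 1, Jun, lower (log2 −0.384, adjusted p = 0.0181) in replicate 2 in the blocked fit, while Myc, Nfatc1 and Nfkb1 were not called. Nr4a1, an early target of receptor signalling, stood at 51.7 to 66.1 CPM in the replicate 1 and 98.1 to 117 CPM in the replicate 2 libraries (log2 0.88), and Nr4a2 and the costimulatory receptor gene Tnfrsf4 were higher by 0.69 each. Slc15a2, a peptide transporter gene, stood at 0.135 to 0.479 CPM in replicate 1 and at 4.33 to 6.62 CPM in replicate 2 (log2 4.06, adjusted p = 0.000154). Penk, Cd74, Cd83 and Serpine2 were higher in replicate 2 by 2.04, 1.38, 1.35 and 0.91. Lower in replicate 2 were Ctnnd1 (log2 −4.53), Kcnj8 (−2.38), Tmem176b (−2.34, from 10.1 to 18.4 against 2.26 to 3.38 CPM), Igfbp4 (−0.96) and the integrin gene Itgae (−0.77, from 113 to 143 against 55.6 to 88 CPM).

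Of the 25 lists, 12 were called higher and 5 lower in replicate 2. Markers of CD4 T, NK and gamma-delta T cells were lower (median −0.935, adjusted p = 0.00357, and adjusted p = 0.163 with an estimated correlation), with 2 of 6 called, Cd4 and Sox13. Markers of myeloid and dendritic cells were higher (0.367, adjusted p = 0.00639, and adjusted p = 0.173 with an estimated correlation), with 1 of 7 called, Cd74. Glycolysis genes (median 0.186, adjusted p = 5.89e-08) and inhibitory receptors (0.214, adjusted p = 0.000189) were also higher in replicate 2, and interferon-stimulated genes lower (−0.187, adjusted p = 2.42e-05). No list was called between the numbers with an estimated correlation (smallest adjusted p = 0.154). Penk, Serpine2 and Igfbp4 thus differed with the replicate number as well as with GFP status, and their SDs within a group were large beside the SE of the blocked fit. A division of the libraries by construct, irrespective of GFP, called 0 genes. That fit left the GFP difference in its spread, which can hide differences between the constructs.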
